A study of Oryza sativa with 16 samples.

How the data were processed

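RNA of rice anthers at 8 stages, 2 arrays per stage, had been hybridised to 16 one-colour arrays, from 100 ng of total RNA labelled with Cy3. The intensity values came, per the file headers, from Agilent Feature Extraction 9.5.1.1, which subtracted the local background and detrended each array spatially and multiplicatively, with no normalization between arrays. The same deposited files hold other values that are 0 or 1 flags, for signal well above background, saturation and outlier spots. The deposited series values are ratio values: the background-subtracted signal of a probe divided by the median of its array, with a minimum of 0.01, which was checked against the scanner files. Those ratios were used only as an alternative.

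Each array had 45151 spots. Control spots (2007, of which 590 were named as controls but not marked as such) were left out, and spots of the same probe were averaged to 42418 probes. Of these, 510 named after microRNAs and 19 without a locus of their own were left out of the gene tests, which left 41889 probes of 29644 loci. A further 86 were left out for an outlier flag. The processed signal was divided by the 75th percentile of its array. Values under 0.0284 of it, the highest of the 16 arrays' lowest signals well above background, were raised to that floor (-5.14 in log2). Probes well above background on both arrays of at least 1 stage were kept (38436), and each gene was represented by its probe with the highest mean over all arrays, which gave 27059 genes, 7261 of them with more than 1 kept probe. Between 14.04% and 24.14% of the tested values of an array lay at the floor. The well-above-background flag was lenient: 2.5% to 75% of the random-sequence control probes carried it. A gene not well above background on either array of a stage had its change given, where stated as at least a fold, as a lower bound, computed from the other stage's mean over, on each dim array, the higher of the probe's own signal and the lowest signal well above background on that array. Such a bound holds for the stage mean and not for each array. It can exceed the fitted change, in which the common floor replaces lower signals.

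A linear model with 8 stage means was fitted in limma 3.58.1 (R 4.3.3, data.table version 1.17.8), with 8 residual degrees of freedom and 1.03 prior degrees of freedom. The 7 steps between adjacent stages were tested, later minus earlier, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 change of at least 1. All tests were two-sided. A moderated F test compared the 8 stages. Stage-peak genes passed both limits against each of the 7 other stages. Among called genes with several kept probes, all probes moved the same way in 89.4% to 96.4% of cases per step.

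Camera tested 20 gene lists at the 7 steps with an estimated correlation between genes, adjusted over 140 pairs. The 10 lists of written loci covered anther patterning, tapetum regulators, tapetum and exine, meiosis, starch, sugar transport, late pollen, gibberellin, jasmonate and markers of other floral parts. The 10 lists found by keyword in the descriptions covered core histones, ribosomal proteins, photosynthesis, expansins and pollen allergens, pectin modification, lipid transfer, kinesins, cyclins, the proteasome and heat shock proteins. Symbols and loci of the first 10 were paired from general knowledge of rice and checked against the descriptions: of 127 loci written, 124 were on the array, 2 were dropped for their description and 122 were tested. Of the 127 loci written, a reference table held the symbol of 78, and it placed 74 of these symbols on the chromosome of the locus but not TIP3, MTR1, DMC1B and ZIP4. The keyword cyclin also matched 2 genes with the word recycling, the pectin keywords matched 23 inhibitors, and the heat shock keywords matched 66 genes described as DnaJ. The genome build is not given in the sources used here.

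The lists, the tests, the thresholds, the alternatives other than those named as added, and the rule for naming genes were chosen before the data were examined. The rule allowed for naming, per step, the 6 largest rises and 6 largest falls among called genes with an informative description and arrays that did not overlap, per stage the 4 clearest peak genes, and any list member. Not all genes that it allowed are named below.

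The gene and list tests, but not the background, scaling, filter and probe steps, were run on simulated values of 27059 genes. Among these, 50 genes were planted at each size and step, all more than 3 (log2) above the floor at the earlier stage. Planted changes were rises and falls, and the falls were cut at the floor. At a log2 change of 1.5, 54% to 66% were recovered, at 2 66% to 84%, at 3 86% to 92% and at 5 92% to 100%, with 5 to 12 false calls per step. Of 200 planted peak genes 150 were recovered, with 0 false. The planted peak genes were also chosen above the floor, so that these rates do not cover changes from or near it. A planted list, simulated without a floor, had an adjusted p of 0.000179 in camera with an estimated correlation. The noise there was also independent between genes, so that this does not show whether camera can detect lists of correlated genes. Such noise holds no slide or scan-day effect shared by genes. On the real arrays, slide and scan day as random blocks had correlations of 0.711 and 0.45. Recovery and false calls may therefore differ on the real arrays.

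Alternatives were another background correction (normexp, offset 50), quantile, median and 75th percentile scaling, the last over probes well above background on all arrays, no filter and a stricter filter (well above background on all 16 arrays), the mean of a gene's probes, the series' own values, replicate number as a fixed block, slide and scan day as random blocks, array weights, no fold minimum, each array left out in turn, and for lists a preset correlation of 0.01 and fry. Added after the data were seen were lower floors, a trended robust variance, slide and scan day as fixed factors, leaving out the 2 dimmest early arrays, and Fisher's exact test for lists. The 16 arrays lay on 8 slides and were scanned on 6 days. Over 9 pairs of stages with the same 2 replicate numbers, residuals correlated across genes at -0.156 to 0.395, 2 above 0.1. The highest was that of P2 with P3, whose arrays of the same number shared a scan day, those of replicate 3 also a slide. That value cannot tell pairing from batch. The numbers were not taken to pair the arrays.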

Results

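Gene expression was measured in rice anthers of the cultivar Nipponbare at 8 stages of development, from the formation of archesporial cells to mature pollen. Each stage had 2 biological replicates, so that 16 one-colour oligonucleotide arrays were analysed, each hybridised with Cy3-labelled RNA made from 100 ng of total RNA. The stages were archesporial cell formation (An1), the S and G2 phases before meiosis (Mei1), leptotene (M1), zygotene to pachytene (M2), diplotene to tetrad (M3), uninucleate microspore (P1), bicellular pollen (P2) and tricellular, mature pollen (P3). The 75th percentile of the processed signal ranged from 478 on An1 replicate 1 to 1935 on P1 replicate 2, and 70.3% to 91.8% of probes were well above background. Genes are named by their locus and by the description in the scanner files. Changes are log2 differences of the scaled signal, later stage minus earlier stage, with the SE of the limma fit and 2 arrays per stage. This SE pools the spread over all 8 stages and can understate that of the stages compared. For Os09g0256100 from M3 to P1 it was 0.61, while the SD of the P1 arrays was 1.77. Where both arrays of a stage lay at the floor of the scale (-5.14), the size of a change depends on the floor and its SE does not cover that. The number of arrays limits the precision of every value.

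Of 27059 genes tested, 20576 (76.0%) differed among the 8 stages in limma's F test at an adjusted p under 0.05. Across genes, which are not independent replicates, the 2 arrays of a stage correlated at 0.969 to 0.994. The highest value was that of M1, the only stage with both arrays on 1 slide. As random blocks, slide and scan day had correlations of 0.711 and 0.45. No slide or scan day held An1 or Mei1 together with a later stage, so that batch and stage cannot be told apart in those comparisons. Neighbouring stages correlated at 0.74 to 0.77 between P1 and P2, the lowest of the 7 steps. Along the first principal component, which held 56.1% of the variance, the arrays of P2 and P3 lay at 167.5 to 305.8 and those of the 6 earlier stages between -112.4 and -31.4. The counts below came from 1 fit to all arrays, and leaving out any array gave 19639 to 20870 genes in the F test.

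**Figure D1:**
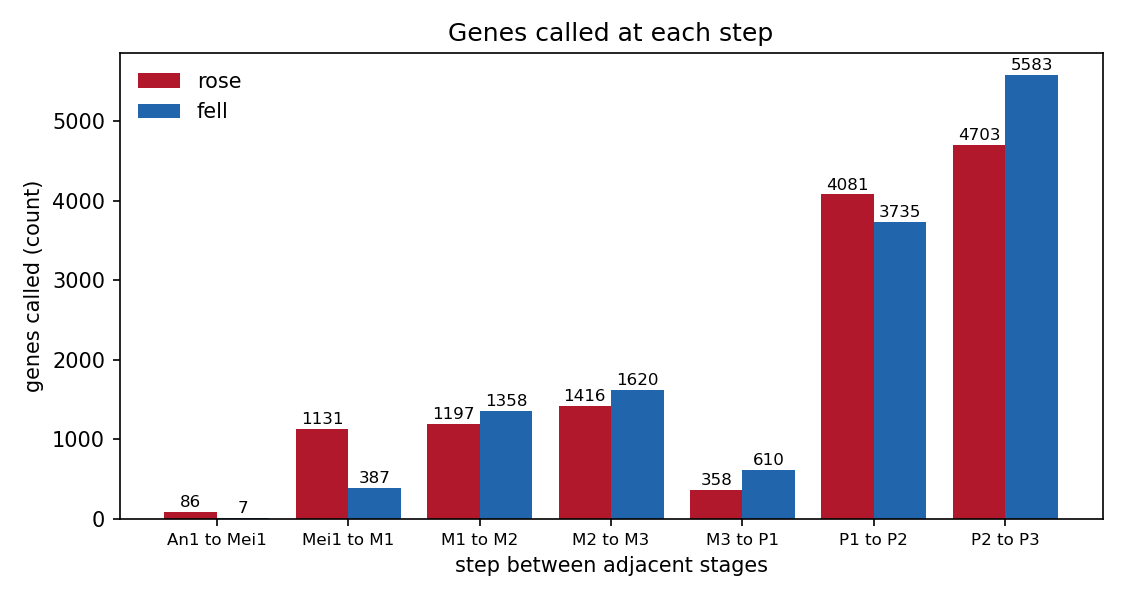
Number of genes that rose or fell at each step between adjacent stages (bars, genes; 2 arrays per stage). There were 86 rises and 7 falls between An1 and Mei1, 3036 calls between M2 and M3, 968 between M3 and P1, and 4703 rises and 5583 falls between P2 and P3.

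Between An1 and Mei1, that is, between the formation of archesporial cells and the phases before meiosis, most changes were rises. Genes of ribosome-inactivating proteins, enzymes that depurinate ribosomal RNA, were among them, Os03g0688000 rising by 4.81 ± 0.46 and Os03g0687800 by 4.04 ± 0.61, the latter not called under 16 of 33 alternatives. A cellulase gene (Os10g0545500) rose by 4.47 ± 0.42, a P450 gene (Os07g0603700) by 4.33 ± 0.60, an aspartic peptidase gene (Os08g0207800) by 4.00 ± 0.21 and a glycerol acyltransferase gene (Os02g0114400) by 3.98 ± 0.49. At An1 1 of the 2 arrays was well above background for Os10g0545500, Os07g0603700, Os03g0687800 and Os08g0207800. A proline-rich protein gene (Os06g0168700) fell by 1.80 ± 0.22 and a cysteine proteinase gene (Os01g0971400) by 1.19 ± 0.16, the latter not called under 13 of 33 alternatives. The gene of a ribosomal protein L40e (Os05g0457400) was not well above background on either array at Mei1. By the lowest signals that passed this lenient flag it was at least 4.98-fold lower, while the fit, which placed it at the floor there, gave -1.08. GA20ox3, an oxidase of gibberellin synthesis, rose by 1.82 ± 0.27, from the floor and with 1 of 2 arrays well above background at An1, and was the only 1 of 14 gibberellin genes called. That list had an adjusted p = 0.692 with an estimated correlation, and its direction reversed with the stricter filter (0.881). Of the genes named here as called, all but Os03g0688000, Os10g0545500 and Os08g0207800 lost the call without at least 1 single array. None of 22 meiosis genes, 19 tapetum and exine genes or 9 tapetum regulators was called over all genes, while 1, 4 and 2 of them rose when adjusted over the list alone. The adjusted p with an estimated correlation was 0.172 for meiosis, 0.516 for tapetum and exine and 0.172 for tapetum regulators. DMC1B, the meiotic strand-exchange recombinase, had a change of 1.60 ± 0.28 that did not pass; the reference table placed this symbol on another chromosome than the locus used here (Os11g0146800). Across genes the difference between the Mei1 arrays correlated at -0.33 with the step. In all, 86 genes rose and 7 fell. Their number was 45 without An1 replicate 1, 48 without Mei1 replicate 2, 28 without both of these arrays (18 of the 93 among them), 51 with another background correction, 49 with the stricter filter and 57 with array weights. It was 168 with slide as a random block, 18 with scan day and 0 with slide as a fixed factor, and 90 of the 93 genes moved at least 2-fold the same way in the pair of arrays that shared a slide, which also entered the call.

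Between Mei1 and M1, the entry into meiotic prophase, 4 of 8 jasmonate synthesis genes and 4 of 14 gibberellin genes rose. YY1 (Os09g0525500), annotated as the precursor of the YY1 protein, rose by 8.64 ± 0.68, a lipoxygenase L-2 gene (Os03g0738600) by 8.08 ± 1.02 and an alpha-amylase gene (Os08g0473900) by 7.47. The last 2 were well above background on 1 of 2 arrays at Mei1, as were a P450 gene (Os12g0582700), which rose by 7.18 ± 0.99, and a gene described as PGPS/D12 (Os03g0830500), which rose by 7.03 ± 0.32. A GDSL lipase gene (Os06g0725200) was at least 255-fold higher at M1 and not well above background at Mei1. Of 8 jasmonate synthesis genes 4 rose, none fell and 4 did not pass, and the count was 4 when adjusted over the list alone. Among them LOX-RCI1, a lipoxygenase, rose by 4.69 ± 0.41, AOS1, the allene oxide synthase, by 2.39 ± 0.38 and OPR7, an oxophytodienoate reductase, by 1.09 ± 0.21. LOX-RCI1, like GA3ox1 below, lay at the floor at Mei1 with 1 of 2 arrays well above background. The list had an adjusted p = 0.172 with an estimated correlation. Of 14 gibberellin genes 4 rose, 5 adjusted over the list alone, with GA2ox3 at 4.06 ± 0.62 and GA3ox1 at 2.32 ± 0.39, and the list again had an adjusted p = 0.172 with an estimated correlation. Thionin genes, which encode small antimicrobial proteins, fell by 3.72 ± 0.62 (Os06g0514100) and 3.62 ± 0.20 (Os06g0512700), and a phoratoxin gene (Os06g0514800) by 3.55 ± 0.27. Small heat shock genes Os01g0136100 and Os04g0445100 fell by 4.60 ± 0.72 and 3.69 ± 0.94, the latter not called under 19 of 31 alternatives, within a heat shock list of 142 genes of which 5 rose and 6 fell, also adjusted over the list alone. The heat shock list had an adjusted p = 0.899 with an estimated correlation, and its direction reversed with another background correction (0.996). MEL1, an argonaute of germ cells, fell by 1.23 ± 0.26, and SDS, a meiotic cyclin-like protein, rose by 1.76 ± 0.07 as the only meiosis gene called. The meiosis list had an adjusted p = 0.904 with an estimated correlation and the other direction with fry (0.708). The calls of MEL1 and OPR7 ended without any 1 of the 4 arrays of these stages, that of GA3ox1 without M1 replicate 2 and that of Os06g0514100 without M1 replicate 1. Of 45 kinesin genes 4 fell, 8 adjusted over the list alone, with an adjusted p = 0.172 with an estimated correlation. Across genes the difference between the Mei1 arrays correlated at 0.44 with the step. Limma called 1131 rises and 387 falls. Rises made up 74.5% of the calls, but 58.2% with quantile normalization and 60.0% with median scaling, which lowered the median of 16089 genes by 0.11. Without Mei1 replicate 2 the number was 700, without M1 replicate 1 809, without M1 replicate 2 749 and without the 2 dim arrays 712 (630 of them in common), and with another background correction or the stricter filter it was 953 or 799; no slide or scan day held both stages, so that batch and stage cannot be told apart here.

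Between M1 and M2, from leptotene to zygotene and pachytene, 11 of 19 tapetum and exine genes rose, while 6 of 22 meiosis genes and 29 of 45 core histone genes fell. Of 19 tapetum and exine genes 11 rose and 1 fell, also when adjusted over the list alone, and 7 did not pass. C4, a lipid transfer protein of the tapetum, rose by 9.14 ± 0.70, PKS2, a polyketide synthase of sporopollenin synthesis, by 9.07 ± 0.60, and DPW, a fatty acyl reductase of the exine, by 8.06 ± 1.07. The M2 arrays stood apart for several of the list's genes: on replicate 1 and replicate 3, DPW lay at 2.73 and 7.06, ABCG15 at 2.35 and 4.85, PKS1 at 3.54 and 5.91 and AP37 at -0.53 and 5.81. By the mean of its M2 arrays ABCG15, a transporter of exine precursors, was at least 1864-fold higher at M2, against 427-fold in the fit. It was not well above background at M1. GPAT3, an acyltransferase, fell by 4.44. The list's median was 4.78, with an adjusted p = 0.269 with an estimated correlation. Of 9 tapetum regulators 3 rose, namely MYB80 by 7.99 ± 0.83, PTC1 by 6.53 ± 0.63 and TDR by 1.75 ± 0.25, and UDT1 fell by 2.52 ± 0.55; the counts were 3 and 2 adjusted over the list alone, with an adjusted p = 0.269 with an estimated correlation. A glycoside hydrolase gene (Os02g0596200) rose by 9.77 ± 0.56 and ribosome-inactivating protein genes Os03g0687700 and Os03g0683300 by 9.63 ± 0.73 and 8.36 ± 0.89. Of 31 lipid transfer protein genes 12 rose and 1 fell (14 and 2 adjusted over the list alone), with Os01g0219500 at 7.16 ± 0.63 and an adjusted p = 0.315 with an estimated correlation.

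Among the falls of the same step, MEL1 fell by 5.57 ± 0.26. Of 22 meiosis genes 6 fell and 16 did not pass, 7 falling when adjusted over the list alone: the locus taken as DMC1B fell by 2.23 ± 0.28, DMC1A by 1.83 ± 0.35, REC8, the meiotic cohesin, by 1.81 ± 0.14, SDS by 1.38 ± 0.07, and SPO11-1 and SPO11-4, of the break-forming family, by 1.08 and 1.01. Of 45 core histone genes 29 fell, 30 adjusted over the list alone, and none rose, with a histone H2A gene (Os03g0721900) at -2.60 ± 0.30. Both lists had an adjusted p = 0.172 with an estimated correlation. Of 11 anther patterning genes 4 fell, also adjusted over the list alone, MEL1, the receptor kinase MSP1, its ligand TDL1A and MADS6, with an adjusted p = 0.218 with an estimated correlation. The calls of DMC1A, SPO11-1, SPO11-4, TDL1A, MADS6 and UDT1 ended without at least 1 array of these stages, and the change of MADS6 was -1.06 without M1 replicate 1 and -1.84 with it. The P450 gene Os07g0603700 and the cellulase gene Os10g0545500, which had risen at Mei1, fell by 5.53 ± 0.60 and 4.81 ± 0.42. A SAUR gene (Os09g0546000) fell by 4.90 ± 0.47, a bHLH gene (Os08g0260400) by 4.90 ± 0.51 and a heavy metal transport gene (Os03g0383900) by 4.66 ± 0.50. Of 44 genes with the keyword cyclin 3 rose and 10 fell (3 and 11 adjusted over the list alone), and of 45 kinesin genes 4 fell, both with an adjusted p = 0.269 with an estimated correlation. Limma called 1197 rises and 1358 falls. The number was 1479 without M1 replicate 1, 1560 without M2 replicate 3, 1707 without M1 replicate 2, 1371 with the stricter filter and 1217 with slide as a fixed factor, and 2136 of the 2555 genes moved at least 2-fold the same way on the shared scan day, on arrays that also entered the call.

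**Figure D2:**
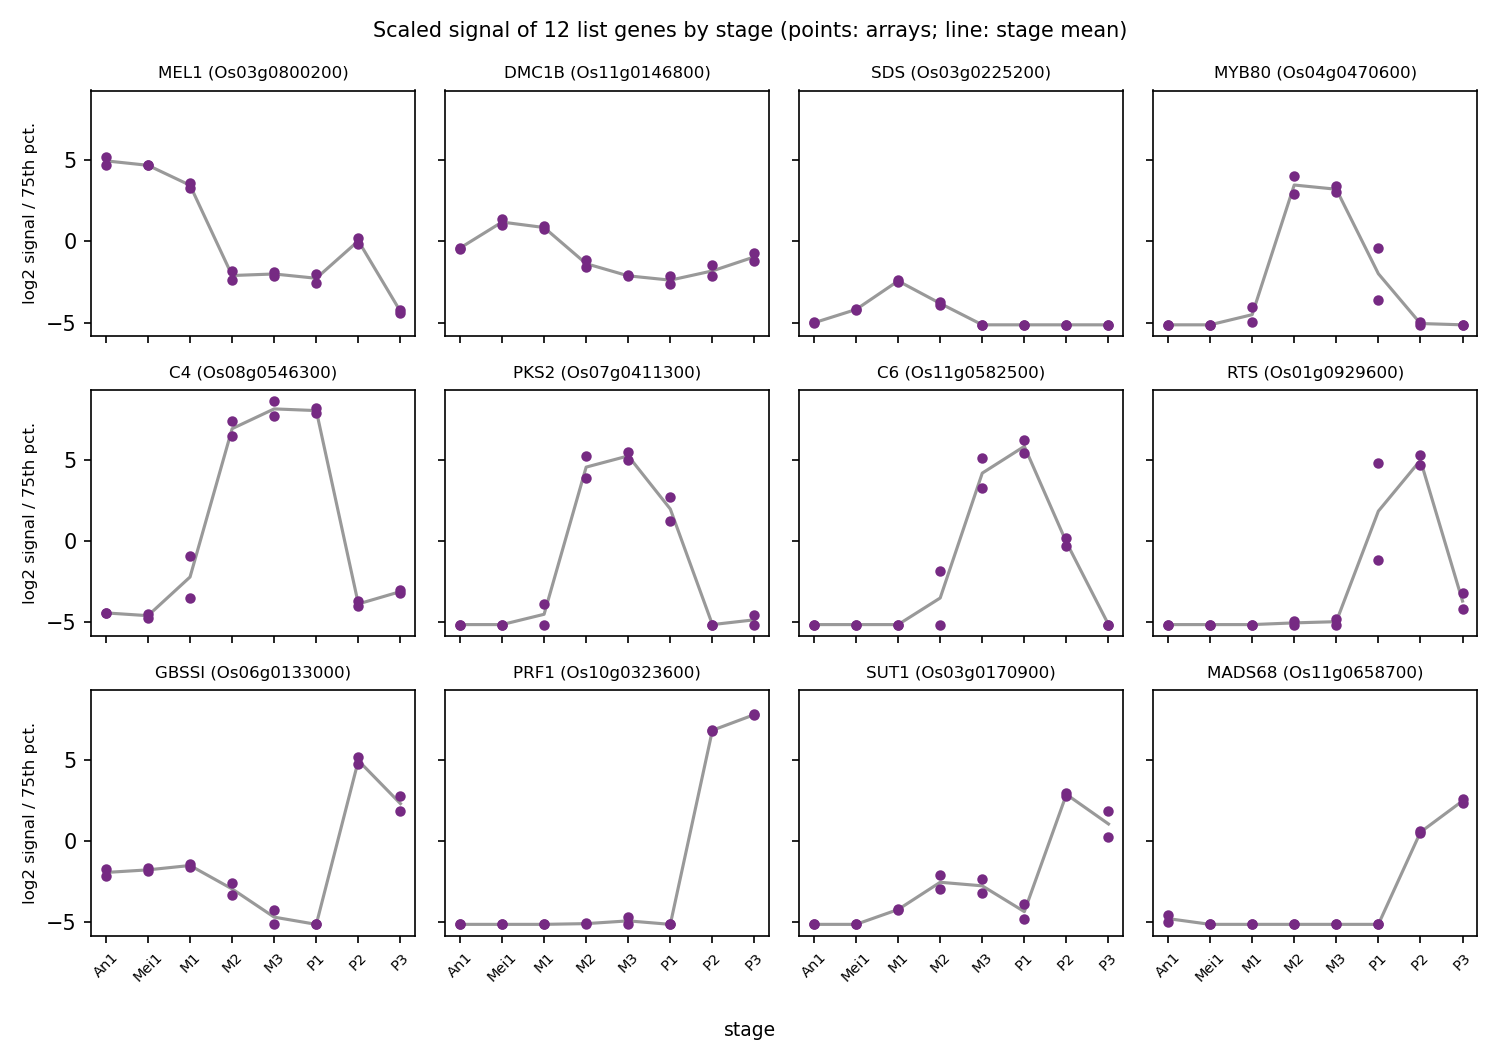
Scaled signal (log2 of signal over the array's 75th percentile) of 12 list genes by stage; points are single arrays, 2 per stage, and the line is the stage mean. MEL1 lay at 3.47 at M1 and -2.10 at M2, C4 at 6.94 at M2, and PRF1 at 6.83 at P2 after -5.14 at P1.

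Between M2 and M3, from pachytene to tetrads, 13 of 31 lipid transfer protein genes and 12 of 42 photosynthesis genes rose and 4 of 8 jasmonate genes fell. A subtilase gene (Os05g0368700) was at least 1619-fold higher at M3 and not well above background at M2. C6, a lipid transfer protein, rose by 7.70 ± 0.92, AP25, an aspartic protease of tapetal cell death, by 4.76 ± 1.07 and CP1, a cysteine protease, by 3.10 ± 0.78, and no other of the 19 tapetum and exine genes was called, also adjusted over the list alone. EAT1, the regulator upstream of AP25, rose by 2.36 ± 0.60 and TIP2 fell by 1.43. The M2 arrays stood apart for AP25 (-1.77 and 2.62), CP1 (-5.12 and -2.08), C6 (-5.14 and -1.86) and EAT1 (-0.13 and 1.69). Without M2 replicate 1 the rises of AP25, CP1 and EAT1 were 2.57, 1.58 and 1.45, and the calls of AP25, CP1, EAT1, TIP2 and the jasmonate gene AOC ended without at least 1 array of these stages. The exine list had an adjusted p = 0.561 with an estimated correlation. Amino acid transporter genes Os06g0228500 and Os06g0228800 rose by 7.57 ± 0.39 and 6.73 ± 0.21, both from the floor. At M2 Os06g0228800 was well above background on 1 of 2 arrays. A gene described as ZmGR1a (Os02g0662100) rose by 7.10 ± 0.53 and a purple acid phosphatase gene (Os12g0637000) by 6.90 ± 0.48. CSA, a regulator of sugar partitioning, rose by 2.21 ± 0.29. Of 31 lipid transfer protein genes 13 rose and 2 fell (14 and 3 adjusted over the list alone), with an adjusted p = 0.51 with an estimated correlation. The dehydrin gene RAB16B (Os11g0454200) fell by 8.19 ± 0.42, a gene of an embryonic abundant protein (Os05g0349800) by 6.35 ± 1.03, a PTI5 factor gene (Os04g0399800) by 7.04 ± 0.38 and an esterase gene (Os03g0790500) by 6.93 ± 0.19. A gene described as a repeated interspersed sequence (Os02g0649300) fell by 6.80 ± 0.89 and the GDSL lipase gene Os06g0725200 by 6.04 ± 0.51. Of 8 jasmonate genes 4 fell, also adjusted over the list alone, LOX-RCI1 by 5.14 ± 0.41, OPR1 by 4.16 ± 0.54, AOS1 by 2.06 ± 0.38 and AOC, with an adjusted p = 0.172 with an estimated correlation. Photosynthesis genes, taken as markers of green tissue, rose in the same step in 12 of 42 cases, 18 adjusted over the list alone, with a median of 1.38 and an adjusted p = 0.516 with an estimated correlation. Limma called 1416 rises and 1620 falls. The number was 1764 with the stricter filter and 1989 with slide as a fixed factor, and 2863 of the 3036 genes moved at least 2-fold the same way on the shared scan day, on 3 of the 4 arrays that entered the call.

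Between M3 and P1, from tetrads to free microspores, 17 of 45 core histone genes and 3 of 9 tapetum regulators fell. A gene described as P450-like (Os01g0183500) rose by 5.83 ± 0.66, a cycloartenol synthase gene (Os08g0223900) by 5.80 ± 0.89 and a lipase gene (Os06g0635300) by 5.68 ± 0.70. A P450 gene (Os05g0482400), a sulfotransferase gene (Os09g0256100) and a transferase gene (Os08g0174100) rose by 5.33 ± 0.85, 5.15 ± 0.61 and 5.14 ± 0.91. RTS, a tapetum gene required for fertility, rose by 6.81 ± 1.44, with -1.14 on P1 replicate 1 and 4.85 on P1 replicate 2, and was not called under 11 of 33 alternatives. The P1 arrays also stood apart for MYB80 (-0.39 and -3.59), Os08g0223900 (-0.94 and 2.79) and the thaumatin gene Os11g0703000 (-1.79 and -5.09), and across genes their difference correlated at 0.5 with the step. Without P1 replicate 2 the change of RTS was 3.82 and that of TKPR1 -2.85, and without it the calls of TKPR1, PKS2, TIP2, PTC1, Os05g0482400 and Os08g0174100 ended. Of 9 tapetum regulators 3 fell, also adjusted over the list alone, MYB80 (-5.21 ± 0.83), PTC1 (-2.83 ± 0.63, not called under 19 of 33 alternatives) and TIP2 (-1.89), with an adjusted p = 0.172 with an estimated correlation. Of 19 tapetum and exine genes RTS rose and 3 fell (4 adjusted over the list alone), the locus taken as MTR1 (Os02g0491300, -5.81 ± 0.40), a symbol that the reference table placed on another chromosome, TKPR1 (-4.51) and PKS2 (-3.27 ± 0.60), with an adjusted p = 0.667 with an estimated correlation. A thaumatin gene (Os11g0703000) fell by 8.62 ± 0.81, and so did an eggshell-family gene (Os05g0498200, -8.35 ± 0.70), a hydroxyproline-rich glycoprotein gene (Os03g0245300, -7.77 ± 0.99) and a chorismate mutase gene (Os12g0578200, -6.71 ± 0.61). An aspartic peptidase gene (Os04g0595000) fell by 6.49 ± 0.31 and a lipid transfer family gene (Os03g0663900) fell by 6.47 ± 0.34. Of 45 core histone genes 17 fell and 1 rose, 18 and 1 adjusted over the list alone, with an adjusted p = 0.257 with an estimated correlation. Of 45 kinesin genes 9 fell (11 adjusted over the list alone), and of 44 cyclin-keyword genes 8 fell and 1 rose (10 and 1), with an adjusted p = 0.461 and 0.265 with an estimated correlation. Limma called 358 rises and 610 falls. The number was 468 without P1 replicate 2, 363 with the stricter filter, 590 with the series' own value table, 1668 with slide as a random block, 333 with scan day and 46 with slide as a fixed factor (296 and 35 in common with the 968). On the shared scan day 871 of the 968 genes moved at least 2-fold the same way, on arrays that also entered the call.

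Between P1 and P2, the first pollen mitosis, 11 of 13 starch genes rose and 14 of 19 tapetum and exine genes fell, and 7816 genes were called in all. A glutelin gene (Os09g0405200) was at least 15378-fold higher at P2, a beta-expansin gene (Os10g0548600) at least 11318-fold, an invertase and pectin methylesterase inhibitor gene (Os05g0543000) at least 11001-fold and a pollen allergen gene (Os04g0317500) at least 9027-fold, none of them well above background at P1. PRF1, a profilin, rose by 11.96 ± 0.12 and a beta-amylase gene (Os10g0465700) by 12.03 ± 0.76. Of 13 starch genes 11 rose, none fell and 2 did not pass, also adjusted over the list alone. GBSSI, the amylose synthase, which was well above background on 1 of 2 arrays at P1, rose by 10.10 ± 0.39, AGPL4, a subunit of ADP-glucose pyrophosphorylase, by 4.93 ± 0.35 and the branching enzyme BEIIb by 4.29 ± 0.34, with an adjusted p = 0.269 for the list with an estimated correlation. Of 7 late pollen genes 5 rose and none fell, also adjusted over the list alone, with PRF2, at the floor at P1 and well above background there on 1 of 2 arrays, at 11.02 ± 0.13, UGP2, a UDP-glucose pyrophosphorylase, at 7.97 ± 0.57 and MADS63 at least 230.3-fold higher, and an adjusted p = 0.172 with an estimated correlation. Of 12 sugar genes 6 rose and 3 fell, also adjusted over the list alone. The monosaccharide carrier MST5 rose by 7.46 ± 0.34, the sucrose carrier SUT1 by 7.23 ± 0.53, SUT3 was at least 139.6-fold higher and CSA fell by 6.07 ± 0.29. The list had an adjusted p = 0.51 with an estimated correlation, and its direction reversed with the stricter filter (0.448). That filter needs signal well above background on all 16 arrays and so leaves out SUT3. Of 14 gibberellin genes 8 rose and 3 fell, also adjusted over the list alone, among them KAO by 8.58 ± 0.26, GA2ox1, which inactivates gibberellins, by 8.38 ± 0.80, CPS1, the first committed enzyme, by 8.07 ± 0.17, also from the floor with 1 of 2 arrays well above background, GA3ox1 by 7.62 ± 0.39 and GA20ox3 by 5.41 ± 0.27, with an adjusted p = 0.218 with an estimated correlation. Of 67 expansin and pollen allergen genes 30 rose and 12 fell (30 and 13 adjusted over the list alone), and of 82 pectin-modifying genes 33 rose and 16 fell, also adjusted over the list alone, with an adjusted p = 0.172 and 0.269 with an estimated correlation. The direction of both lists reversed with the stricter filter (0.329 and 0.551). That filter leaves out genes dim on any array of any stage. Among these were 471 called rises from a dim P1 and 117 called falls to a dim P2. Of the 7816 calls, 4704 were also made in the same direction with that filter. The reversal therefore cannot weigh the rises from a dim P1. The pectin keyword also matched 23 genes described as inhibitors, of which 11 rose.

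Falling at that step, 14 of 19 tapetum and exine genes and 7 of 9 tapetum regulators declined, also adjusted over the list alone, while GPAT3 rose by 1.82. C4 fell by 11.92 ± 0.70, as did CYP704B2, a fatty acid hydroxylase of sporopollenin synthesis (-11.74 ± 0.66), PKS1 (-11.52 ± 0.60) and ABCG15 (-9.34 ± 0.63), and AP25 was at least 3605-fold lower. PTC1, EAT1, UDT1 and MYB80 fell by 4.16, 3.14, 3.11 and 3.07. For MYB80 the change was -1.47 without P1 replicate 1 and -4.67 without P1 replicate 2, and its call ended without either P2 array, as did that of GPAT3 without P2 replicate 3 or either P1 array. The lists had an adjusted p = 0.356 and 0.172 with an estimated correlation. The subtilase gene Os05g0368700 fell by 11.19 ± 0.22, as did a gene of an AMP-dependent synthetase (Os04g0310800, -10.94 ± 0.39) and YY1 (Os09g0525500, -10.83 ± 0.68); CYP704B2, PKS1, Os05g0368700 and Os04g0310800 were well above background on 1 of 2 arrays at P2. Photosynthesis genes fell in 16 of 42 cases, also adjusted over the list alone, with a median of -1.36 and an adjusted p = 0.561 with an estimated correlation. Of 8 jasmonate genes 2 rose and 1 fell, also adjusted over the list alone, with an adjusted p = 0.899 with an estimated correlation. The jasmonate direction reversed with the stricter filter (0.973) and without P2 replicate 3 (0.969). Of 292 ribosomal protein genes 54 rose and 22 fell (54 and 23 adjusted over the list alone), with an adjusted p = 0.685 with an estimated correlation. Limma called 4081 rises and 3735 falls. With the stricter filter, which left fewer genes to test, the number was 4869, and 7396 of the 7816 genes moved at least 2-fold the same way on the shared slide, on arrays that also entered the call.

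**Figure D3:**
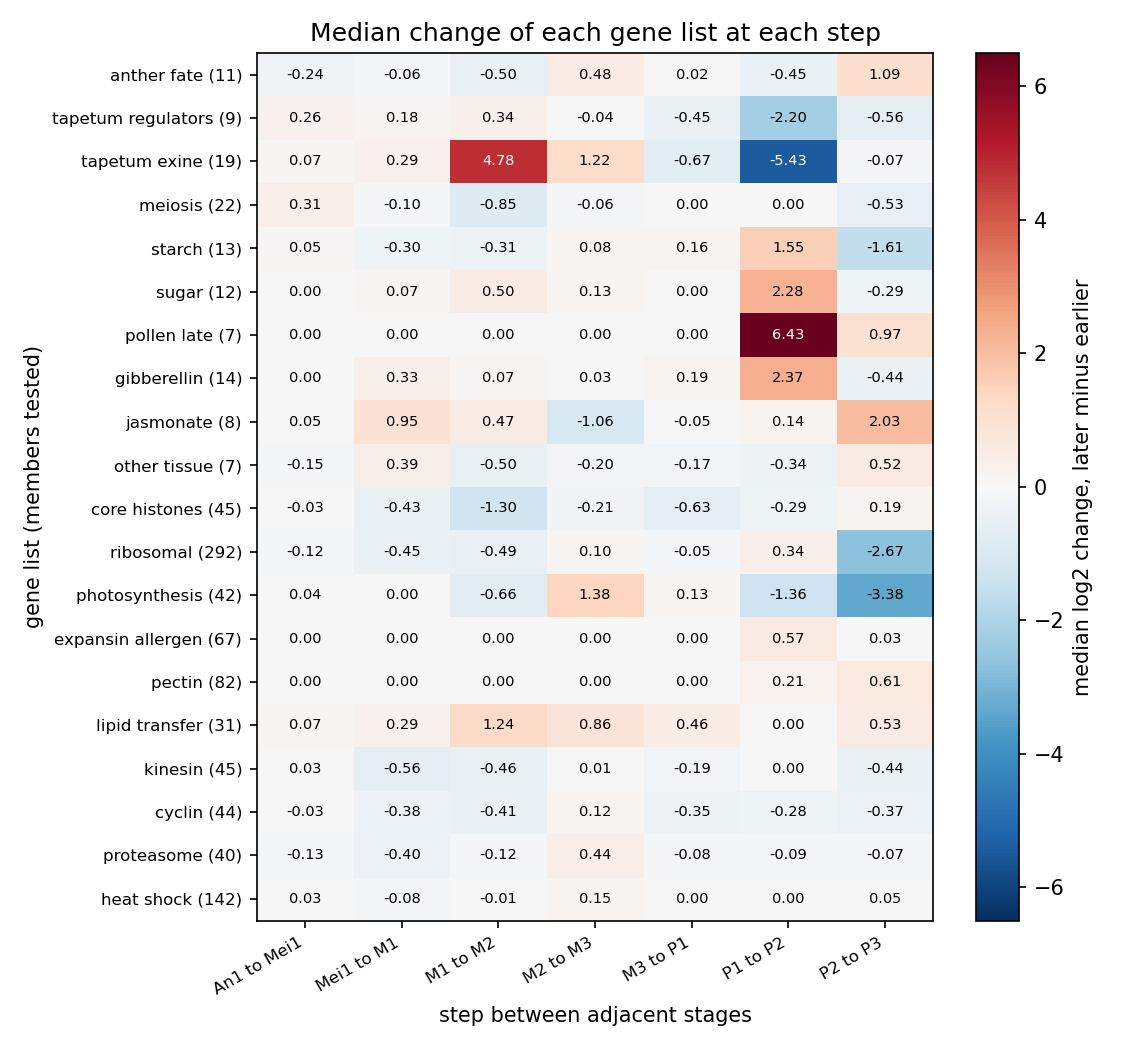
Median log2 change, later minus earlier stage, of each of the 20 gene lists (vertical, number of members tested) at each of the 7 steps (horizontal). The largest medians were 6.43 for late pollen genes and -5.43 for tapetum and exine genes, both between P1 and P2.

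Between P2 and P3, the second pollen mitosis and maturation, most ribosomal protein, photosynthesis and starch genes fell and 6 of 8 jasmonate genes rose. Of 292 ribosomal protein genes 251 fell, 4 rose and 37 did not pass, 252 and 4 adjusted over the list alone. The list's median was -2.67, between -2.81 and -2.37 under other scalings, with an adjusted p = 0.172 with an estimated correlation; the P0 gene Os11g0135400 fell by 4.45 ± 0.16. Of 42 photosynthesis genes 30 fell and 1 rose (31 and 1 adjusted over the list alone), with a median of -3.38 and an adjusted p = 0.461 with an estimated correlation. Of 13 starch genes 10 fell and 1 rose, also adjusted over the list alone, GBSSI by 2.65 ± 0.39 and BEIIb by 1.29 ± 0.34, with AGPL4 rising by 1.01 ± 0.35 (not called under 17 of 34 alternatives) and an adjusted p = 0.51 with an estimated correlation. Of 8 jasmonate genes 6 rose and none fell, also adjusted over the list alone, OPR1 by 3.31 ± 0.54, LOX-RCI1 by 3.04 ± 0.41 and OPR7 by 2.20 ± 0.21, with an adjusted p = 0.269 with an estimated correlation. Of 11 anther patterning genes 7 rose and 2 fell, also adjusted over the list alone: the rises were all MADS genes, among them MADS16 by 1.55 ± 0.19 and MADS3 by 1.51 ± 0.44, the falls were MEL1 by 4.35 ± 0.26 and MSP1, and the adjusted p was 0.492 with an estimated correlation, with the direction reversed under quantile normalization (0.982). Of the markers of other floral parts MADS1 rose by 3.33 and MADS14 by 1.29 ± 0.19, and the other 5 of 7 were not called at this step, nor any of the 7 at the earlier steps. The adjusted p of these markers was 0.662 with an estimated correlation. Without P2 replicate 2 or P3 replicate 3 the calls of MADS3 (0.98 and 0.87), MADS1 (2.24 and 2.52) and BEIIb (-1.17 and -0.66) ended. Of 82 pectin-modifying genes 30 rose and 8 fell (31 and 8 adjusted over the list alone), with an adjusted p = 0.269 with an estimated correlation. Of 22 meiosis genes 7 fell, PAIR2 by 3.16 among them, and SGO1, the protector of centromeric cohesion, rose by 1.37 (not called under 14 of 34 alternatives), also adjusted over the list alone. That list had an adjusted p = 0.558 with an estimated correlation, and its median changed sign under 1 of the other scalings, as did those of the tapetum and exine, tapetum regulator and late pollen lists.

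Among genes with an informative description, the largest rises to P3 were those of an LEA3 gene (Os05g0362600) at 7.63 ± 2.08, a glyoxal oxidase gene (Os01g0677000) at 7.15 ± 1.67, a pectinesterase gene (Os07g0691100) at 7.02 ± 1.80, an R2R3 Myb gene (Os05g0568200) at 6.75 ± 1.52, a phosphatidylinositol kinase gene (Os01g0270700) at 6.67 ± 1.67 and an aquaporin-family gene (Os03g0320000) at 6.60 ± 1.26. These genes were uneven at P2: Os05g0362600 lay at the floor of -5.14 on replicate 2 and at 3.64 on replicate 3, Os01g0677000 at -5.14 and 1.92, and Os01g0270700 at -2.25 and 4.65. Without P2 replicate 2 the 6 rises were 3.21 to 3.98, and without P2 replicate 3 those of Os05g0362600, Os07g0691100 and Os01g0270700 were 12.02, 10.83 and 10.12. Without P3 replicate 3 the calls of Os05g0362600 and Os07g0691100 ended, and Os05g0568200 was well above background on 1 of 2 arrays at P2. In all, 37 genes at the floor on P2 replicate 2 lay above 1 on P3 replicate 3, and all 37 lay above the floor on P2 replicate 3. A gibberellin-regulated protein gene (Os05g0432200) was at least 446.6-fold lower at P3, a kinase gene (Os08g0376300) at least 257.3-fold and a papain-family gene (Os09g0497500) at least 207.4-fold. A lipid transfer family gene (Os04g0415900) fell by 7.99 ± 1.58, as did a thaumatin-like gene (Os07g0419300, -7.65 ± 0.70) and a chitinase gene (Os05g0399700, -6.86 ± 1.77), the last with 1.66 on P3 replicate 2 and -4.58 on replicate 3, a change of -3.74 without P3 replicate 3 and no call without P2 replicate 2. The thaumatin-like gene was well above background on 1 of 2 arrays at P3. RTS fell by 8.68 ± 1.44, and GA2ox6 rose by 5.15 ± 0.48. Limma called 4703 rises and 5583 falls, and 9981 genes in all without P2 replicate 3. Rises were 45.7% of calls, but 65.4% with another background correction and 57.2% with median scaling, which raised the median of 16089 genes by 0.31; 9528 and 9738 of the 10286 genes moved at least 2-fold the same way within the 2 scan days that held both stages, on the arrays that entered the call.

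**Figure D4:**
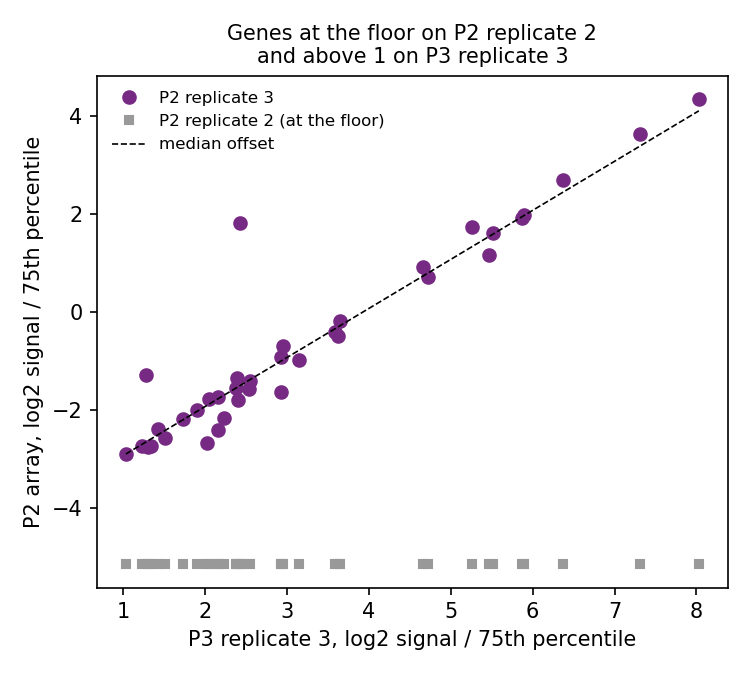
Scaled signal (log2 of signal over the array's 75th percentile) on the 2 P2 arrays (vertical) against P3 replicate 3 (horizontal) for the 37 genes at the floor on P2 replicate 2 and above 1 on P3 replicate 3; points are genes. On P2 replicate 3 they lay at a median of -3.92 relative to P3 replicate 3.

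Stage-peak genes stood above all 7 other stages by at least 1 (log2) with an adjusted p under 0.05 in each comparison. Of 4108 such genes 2749 peaked at P3, 942 at P2, 237 at M2, 128 at P1, 38 at M1, 11 at M3, 3 at An1 and none at Mei1. At An1 the proline-rich gene Os06g0168700 lay 1.21 above the next stage. At M1 a SAUR gene (Os09g0546300) lay 2.82 above the next stage, an adrenodoxin reductase gene (Os04g0224100) 2.59 and a WD40 gene (Os06g0238700) 2.55. At M2 a homeodomain-like gene (Os11g0303800) lay 4.13, an AP2 gene (Os12g0168100) 3.58 and a protein kinase gene (Os11g0553500) 3.56 above the next stage. At M3 a Myb gene (Os11g0207600) lay 2.17 and a dehydrogenase gene (Os07g0664100) 2.03 above. At P1 the P450-like genes Os01g0183500 and Os05g0181200 lay 5.83 and 3.90 above, and a homocysteine methyltransferase gene (Os01g0772900) 4.33. At P2 a cell wall invertase gene (Os04g0413200) lay 6.36, a gibberellin-regulated gene (Os05g0432200) 5.78 and a beta-xylosidase gene (Os11g0297300) 5.19 above. The clearest P3 peak genes were the LEA3, glyoxal oxidase, pectinesterase and R2R3 Myb genes named above for their rises from P2, where their arrays were uneven. Without a single array in turn the total was 3826 to 4192, but at An1 it was 7, 17 and 5 without An1 replicate 1, An1 replicate 2 and Mei1 replicate 2, at Mei1 13 without Mei1 replicate 3 and 1 without P2 replicate 2 or P2 replicate 3, and at M1 24 without Mei1 replicate 2. At M3 it was 83 without M2 replicate 3, 18 and 23 without M3 replicate 2 and M3 replicate 3 and 19 without P1 replicate 1, and at P1 it was 64 and 72 without P1 replicate 2 and M3 replicate 3. With the stricter filter, which left fewer genes to test, the total was 2291.

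Camera called 0 of the 140 pairs of list and step with an estimated correlation, 24 of them at an unadjusted p under 0.05 (7 if no list differed) and the lowest adjusted p at 0.172. It called 53 with a preset correlation of 0.01. Fry, which tests a list for any change and not against the other genes, called 56. Fisher's exact test of called members (two-sided), which treats genes as independent and was added after that count of 0 was seen, called 40 of the 140 pairs in at least 1 direction.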

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

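The test in this part was chosen after the data had been seen. A set of 510 probes named after microRNAs, which the gene tests did not use, held signal above the controls. Of them 147, with 86 names, lay above every random-sequence control on both arrays of at least 1 stage, 90 at An1, 40 at P2 and 25 at P3. More lay above the controls at M1 than at An1. The limit was each array's own highest control, so that these counts may depend on the brightness of the arrays, which was not tested. Among the 147, 51 differed among the stages in limma's F test, and over all 510 probes 39 were called higher and 3 lower at P3 than at P2, of which only 14 and 1 lay above the controls at the stage where they were higher. The 3'seq probe of osa-miR160f lay at -0.77 at P2 and 1.41 at P3, a rise of 2.18 ± 0.27 with an adjusted p of 0.00136, and its mature probe rose by 2.05 ± 0.26. The 3'seq probe of osa-miR171i lay at -1.52 at An1 and -4.94 at P3, and the 5'seq probe of osa-miR166a at -1.77 and -4.91; both lay above the controls at An1 and not at P3. Each value is the mean of 2 arrays. Whether these probes measured mature microRNAs or longer transcripts was not tested, nor was any biological explanation.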

How the results depend on the processing

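Of the alternatives here, lower floors, a trended robust variance, fixed slide and scan day, leaving out 2 dim arrays and Fisher's exact test were chosen after seeing the data. The F test count stayed within 1.5-fold under 32 alternatives (14329 to 22990), as did the count from P2 to P3 under 35 (7384 to 13061). From An1 to Mei1 (93 genes) the count was 51 with normexp, 49 with the stricter filter, 45 with a replicate block, 168 with slide as a random block, 57 with array weights, 18 with fixed scan day, 0 with fixed slide and 28 without the 2 dim arrays. At that step limma called 1262 genes at an unadjusted p under 0.05 with no block, fewer than the 1353 that would pass by chance if no gene changed, and the count with fixed slide came from 2 residual degrees of freedom. From Mei1 to M1 (1518) it was 953 with normexp, 799 with the stricter filter, 712 without the 2 dim arrays and 2740 with no fold minimum. From M1 to M2 (2555) it was 1371 with the stricter filter, 1217 with fixed slide and 4306 with no fold minimum, and from M2 to M3 (3036) 1764, 1989 and 4647. From M3 to P1 (968) it was 363 with the stricter filter, 590 with the series' own values, 1668 with slide as a random block, 333 with fixed scan day and 46 with fixed slide. With the stricter filter it was 4869 from P1 to P2 (7816) and 2291 for stage-peak genes (4108). Lists passed in 0 pairs, but in 53 with a preset correlation and 40 with Fisher's exact test. With fry, which asks for any change in a list and not for a difference from other genes, 56 passed. Leaving out each array in turn, where a lone array is assumed to vary like the other groups, gave 45 to 107, 700 to 1846, 1479 to 2863, 2151 to 3064, 468 to 1119, 6662 to 7855 and 9361 to 10448 genes for the 7 steps. It gave 3826 to 4192 peak genes and 0 list pairs. Of 163 changes of named genes none reversed, 87 lost their call under at least 1 alternative and 75 kept their side of the threshold under all of them; fixed slide ended 68, and no single array left out ended more than 14. None of the list tests below passed, and their direction reversed as follows, with the adjusted p. With normexp it was heat shock from Mei1 to M1 (0.996) and from P2 to P3 (0.968), and other floral parts from M3 to P1 (0.996). With quantile normalization it was anther patterning from P2 to P3 (0.982). With the stricter filter it was gibberellin from An1 to Mei1 (0.881), and from P1 to P2 expansin and allergen (0.329), jasmonate (0.973), pectin (0.551) and sugar (0.448). Other floral parts reversed from M3 to P1 with the mean of probes (0.929), fixed scan day (0.963) and fixed slide (0.967), and from Mei1 to M1 with a replicate block (0.988). With fry it was heat shock from P2 to P3 (0.721) and meiosis from Mei1 to M1 (0.708). Without M1 replicate 1 other floral parts reversed from Mei1 to M1 (0.895 to 0.986 over the arrays left out), without M3 replicate 2 from M3 to P1 (0.724 to 0.98), and without P2 replicate 3 jasmonate from P1 to P2 (0.689 to 0.969). The stricter filter left fewer genes to test and left out those dim on any array, so that it cannot weigh changes from or to a dim stage. Fixed factors left 4 (day) or 2 (slide) residual degrees of freedom and fewer arrays, and dropping the fold minimum adds small changes. For the rest the cause was not tested. Mei1 to M1 was not estimable with fixed day or slide, and lists were not run with random blocks or the trended variance. Signal over background limits what was seen: 14.04% to 24.14% of tested values lay at the floor.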

Other observations

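The tests of the 3 patterns weighed in this part were chosen after the results were seen, except that of matched random lists; the counts and p values of gene lists were planned. Gibberellin genes were called in both directions as pollen matured. From P2 to P3, 3 of 14 rose and 5 fell, also adjusted over the list alone: SLR1, the growth repressor of the pathway, rose by 2.21 ± 0.24, while GA3ox1, which activates gibberellins, fell by 2.62 ± 0.39 and GA2ox3, which inactivates them, fell by 3.19 ± 0.62. The list's adjusted p was 0.885 with an estimated correlation. Of 142 heat shock genes 27 rose and 28 fell at that step, and of 40 proteasome genes 1 rose and 7 fell, both also adjusted over the list alone. Their adjusted p was 0.935 and 0.849 with an estimated correlation, the heat shock direction reversed with another background correction (0.968) and with fry (0.721), and the proteasome median of -0.06 changed sign under 2 of the other scalings. Of 45 kinesin genes 12 rose and 12 fell from P1 to P2 and 8 rose and 17 fell from P2 to P3, also adjusted over the list alone, with an adjusted p of 0.938 and 0.599 with an estimated correlation.

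By the stage of the highest mean, which was not tested, the lists were spread over development. Of 22 meiosis genes 10 were highest at Mei1 and 7 at M1, of 19 tapetum and exine genes 13 at M3, and of 8 jasmonate genes 5 at M2. Photosynthesis genes were highest at P1 in 21 of 42 cases and starch genes at P2 in 7 of 13. Ribosomal protein genes were highest at An1 in 168 of 292 cases and core histone genes in 24 of 45. The ribosomal medians were 2.61 at An1, 2.48 at Mei1 and 2.43 at P2. Of all 27059 genes, 4439 were highest at An1, 2645 at Mei1, 1472 at M1, 3483 at M2, 1460 at M3, 2305 at P1, 3878 at P2 and 7377 at P3. No slide or scan day held An1 or Mei1 together with a later stage, so that batch and stage cannot be told apart there.

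Transcripts of mature pollen appeared on P2 replicate 3. Over the 37 genes at the floor on P2 replicate 2 and above 1 on P3 replicate 3, the difference between P2 replicate 3 and P3 replicate 3, which shared a slide, had a median of -3.92 and an interquartile range of 0.27, against 0.81 for P3 replicate 2. A fixed share of P3 replicate 3 RNA or signal may therefore lie in that array, at 6.63% of the scaled level. In unscaled signal the share would be larger, as the 75th percentile was 1239.1 on P2 replicate 3 and 517.1 on P3 replicate 3. At most 27% of the genes lay above the floor on the 2 other arrays of the slide, which leaves a spread over the slide open. Anthers further along also stay open: over the 5583 genes that fell from P2 to P3 the difference between the P2 arrays had a median of -0.18, with 3835 lower on replicate 3. Of the 4703 called rises, 2869 (61%) were higher on replicate 3, with a median difference of 0.16.

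The fall of ribosomal protein genes from P2 to P3 was weighed against the processing. Under the 5 other scalings and value tables the list's median was at most -2.37. At this step these alternatives shifted genes by only -0.137 to 0.317 from the main scaling. The choice among them therefore cannot account for the fall, while an error shared by all of them cannot be judged this way. Among 10000 random lists matched on the P2 level the lowest median was -0.51, against -2.67, and 0 lists were as low, which argues against an effect of dim P3 arrays on every gene of that level. A biological difference between the stages stays open, as untested.

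The excess of rises from An1 to Mei1 was weighed against the scan day and brightness of the arrays. Of 145 genes at least 2 higher on Mei1 replicate 2 than on An1 replicate 1, 132 were also higher in the pair sharing a slide. The median over the 145 was 2.09 there, which argues against scan day as the whole cause. Brightness cannot be judged this way, as it was close within each pair (75th percentiles of 478 and 509.3, and of 1052 and 1152.8). Of 100 genes at least 2 lower, 67 were lower in the pair sharing a slide, with a median of -0.41. With a lower floor 86% of the called rises were still called, so that an effect of the floor on the others cannot be excluded. The biological difference between the stages stays open, as untested.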
